A study of Mus musculus with 23 samples.

How the data were processed

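Primary exocrine cells of the mouse pancreas, the acinar and duct tissue, were cultured and infected with 2 kinds of adenovirus, and RNA was measured in cells sorted 5 days after isolation. Per the labels' protocols, infection ran overnight and 30 ng of purified RNA entered each library. Each of the 23 libraries was made by bulk MARS-seq, which tags the 3′ end of a transcript and attaches a molecular identifier (UMI), and was sequenced on an Illumina NextSeq, per the labels' protocols.

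The authors deposited 1 table of raw UMI counts per gene for all libraries, and these counts are the only values used here. Per the submitters' processing notes, reads were handled with bcl2fastq, cutadapt 1.8.3, STAR, HTSeq and DESeq2 on the genome builds mm10 and GRCm38. The other versions, the annotation, the strand setting, the rule that collapsed identifiers and any filter on genes are not given in the sources used here. The table holds 13252 genes, each with a highest count of at least 6 in some library and a total of at least 10, so genes below that level were not analysed here. No mitochondrial transcript was among them. Gene symbols are those of the deposited table, of which 12788 (96.5%) matched the GENCODE M21 annotation of GRCm38, the source of the coordinates.

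Groups came from the sample labels, and every column of the table matched 1 label. Library totals ran from 1562738 to 4627215 counts, a 2.96-fold range. Standard errors and standard deviations cover counting error and the spread between these libraries; the interval given with a share of genes covers binomial error over genes and not the spread between libraries. Where a group held 1 to 3 counts of a gene, the ratio of counts per total count is given with an exact binomial interval, which covers counting error alone. All 33 pairs of libraries within groups differed by more than counting noise (chi-square per degree of freedom from 2.08 to 10.2), so no library was treated as a copy of another.

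Differences were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM scaling, filterByExpr, robust dispersion), with 1 coefficient for each of the 6 groups and all 23 libraries in 1 model. The filter left 11384 genes and the model 17 residual degrees of freedom. The p-values measure the spread between these libraries. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2 scale with a prior count of 0.125, given ± standard error (SE), and levels are CPM (counts scaled to a common library total after TMM), computed here from the deposited counts and given as mean ± standard deviation (SD) with n libraries. Where every library of a group had 0 counts for a gene, no standard error or fold was printed.

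There were 8 comparisons. They were mCherry+ against mCherry- cells of the PNM infection with LacZ and again with REST, REST against LacZ in the PNM mCherry+, PNM mCherry- and NGN3 GFP+ cells, PNM against NGN3 cells with LacZ, and the differences of the REST effect between mCherry+ and mCherry- cells and between PNM and NGN3 cells. The groups, the comparisons, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The named genes of a comparison were those the viruses carry, the islet hormones, the 10 highest and the 10 lowest called genes among those with a mean of at least 10 CPM in the higher group and no overlap between the libraries of both groups, and up to 4 called members of each list (or up to 2 of the most abundant where none was called). Genes named outside this rule are said to have been chosen after their values were seen.

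The 20 gene lists were virus genes, beta cell genes, endocrine progenitor genes, other islet hormones and subtype genes, secretory granule and exocytosis genes, RE1-bearing REST target genes, REST corepressor genes, acinar genes, ductal and epithelial plasticity genes, Notch pathway genes, proliferation genes, interferon response genes, unfolded protein response genes, immediate early and heat shock genes, p53 target genes, mitochondrial transcripts, and markers of stromal, immune, endothelial and Schwann cells. They were written from general knowledge and not from these libraries. With fewer than 5 tested members, the virus, mitochondrial and Schwann cell lists were given no list test, which left 17. Of the 34 tested RE1-bearing genes, 10 are also among the 28 tested secretory granule genes. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over the lists of a comparison. Each call was repeated with a correlation estimated from the data. Members were counted over all genes tested and, separately, adjusted over the list alone. The score of a list in a library is the mean of its genes' log2 CPM after centring each gene over all libraries.

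The labels give replicate letters (A, B, E and F in the PNM groups; B, C, E and F with LacZ and B, C and E with REST in the NGN3 groups), and the design text speaks of 4 biological replicates without saying what a letter marks. Whether a letter pairs libraries across groups was checked by correlating their deviations from the group means. For REST against LacZ in PNM mCherry+ cells all 4 pairs had a correlation over 0.1 (from 0.198 to 0.383), so the letters were taken to pair these libraries. No other comparison met that rule. For this contrast the value with the letter as a block is given for the number of calls, the hormones, the share and the overlap. Its other single genes and its list tests have standard errors and p-values from the fit without the block.

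The procedure was tested once per comparison on simulated counts with the real library sizes, the mean level and the dispersion of each gene, and 200 genes changed by a known fold. For REST against LacZ in PNM mCherry+ cells, with 11099 genes, 43.7% of the genes changed by 1.5-fold, 81.7% of those changed by 2-fold and 95.4% of those changed by 4-fold were called. For the same contrast in NGN3 cells, with 11086 genes, the shares were 37.9%, 73.0% and 90.8%, and for the difference of the REST effect between PNM and NGN3 cells, with 11113 genes, 12.5%, 47.6% and 85.5%. False calls made up 4.05%, 7.53% and 3.0% of the calls in these, and 5.88%, 5.0%, 7.14%, 2.2% and 6.08% in the others (in this order: both mCherry+ against mCherry- contrasts, REST in mCherry- cells, its difference to mCherry+ cells, and PNM against NGN3 cells).

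The alternatives were DESeq2 1.42.0, its size factors within edgeR, no filter on low counts, a filter at 10 CPM in at least 3 libraries, a model of only the groups compared, the replicate letter as a block, a correlation estimated from the data and fry for the lists, and each library left out in turn. Thinning all libraries to the lowest total, the leave-one-out fits of single genes, of the overlap and of the share, and DESeq2 for single genes were added after seeing the data. Ins1 and Ins2, Prss1, Prss2 and Prss3, and Cela3a and Cela3b are near-identical copies whose reads the counting could split or drop, so their levels are uncertain. The labels also name a file of DESeq2 results made by the submitters, which was not used here. Some results of single genes that the rule names are not reported here. Figures were drawn with Python 3.11.15.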

Results

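RNA was counted in exocrine cells of the C57BL/6 mouse pancreas that carried either of 2 reprogramming viruses together with a second virus. The PNM virus (called M3 in the labels) carries Pdx1, Neurog3 and Mafa, transcription factors of islet development and of beta cells, and marks cells with mCherry. The NGN3 virus carries Neurog3 alone and marks cells with GFP. The second virus carried LacZ, a bacterial enzyme used as the control, or REST, a repressor that binds RE1 sites and keeps neuronal genes off outside the nervous system. The PNM infection gave mCherry+ and mCherry- sorted cells with LacZ and with REST, at 4 libraries in each of these 4 groups. The NGN3 infection gave GFP+ cells, at 4 libraries with LacZ and 3 with REST. Mean totals were 3358090 counts in LacZ mCherry-, 2588100 in LacZ mCherry+, 3329960 in REST mCherry-, 2315140 in REST mCherry+, 3209930 in NGN3 LacZ and 2532080 in NGN3 REST libraries, over a range from 1562738 to 4627215.

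The transcripts of the virus genes were compared first, because the sort should part infected from uninfected cells. Pdx1 (GRCm38 chromosome 5, 147269959 to 147275848, plus strand) had 33.8 ± 14.2 CPM (SD, n = 4) in LacZ mCherry+ cells and 1.6 ± 0.658 (n = 4) in mCherry- cells, a log2 difference of 4.40 ± 0.48 (SE, adjusted p = 6.65e-08). Neurog3 (chromosome 10, 62133090 to 62134763, plus strand) rose by 5.95 ± 0.544 (adjusted p = 8.69e-10) and Mafa by 3.19 ± 0.739 (adjusted p = 0.000412). Without replicate F of the mCherry- cells, which leaves 1 count of each in that group, the fits gave 7.33 for Neurog3 and 4.28 for Mafa. In NGN3 cells Neurog3 stood at 3.93 ± 0.902 CPM with LacZ (n = 4), below the 26.3 ± 5.55 of PNM cells. With REST in PNM cells Pdx1 (0.49 ± 0.312, adjusted p = 0.602), Neurog3 (0.53 ± 0.28, adjusted p = 0.528) and Mafa (-0.16 ± 0.505) did not pass the test. Neurog3 was higher in 4 of the 4 letter pairs. Rest itself (chromosome 5, 77265491 to 77286432, plus strand) had 0 to 9 counts in every library and was not tested. Its counts per library were 0 to 6 with LacZ and 0 to 4 with REST in PNM mCherry+ cells. They were 1 to 8 and 3 to 9 in mCherry- cells, and 1 to 7 and 1 to 3 in NGN3 cells. These ranges overlap, so the counts show no added Rest transcript in the REST groups. Whether the counted 3′ ends include transcripts made from the viruses is not given in the sources used here, so these counts do not measure the dose of either virus.

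Libraries grouped by sorted population and by reprogramming virus more than by REST. Over the 1000 most variable genes, the first principal component held 71.2% of the variance and the second 16.6%. All 8 PNM mCherry- libraries lay between -56.6 and -48.3 on the first, and the other 15 between 9.04 and 38.2. The second parted the PNM mCherry+ libraries, all positive, from the 7 NGN3 libraries at -26.5 to -22.8.

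**Figure D1:**
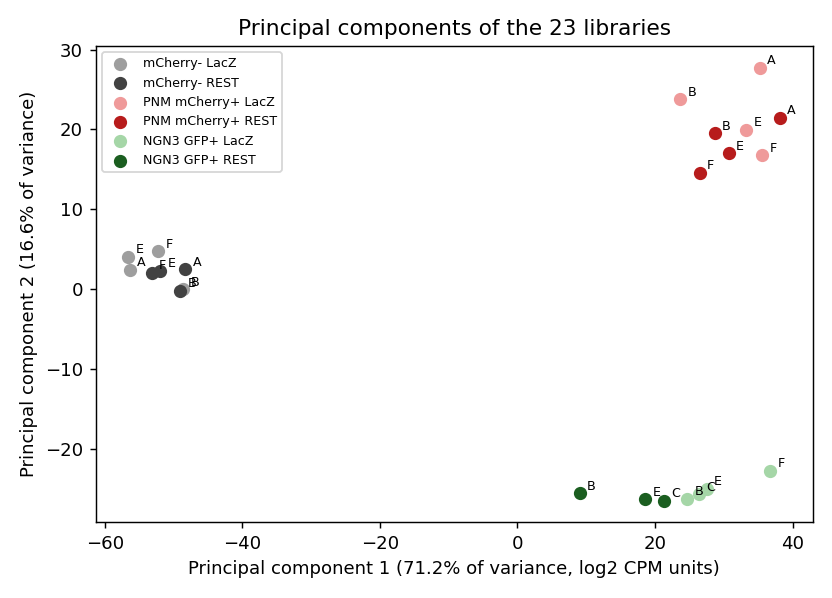
Scores of the 23 libraries on the first and second principal components (percent of variance on each axis), one point per library and one colour per group. The PNM mCherry- libraries sit at -56.6 to -48.3 on the first component, apart from the mCherry+ and GFP+ libraries.

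The first comparison asked how cells that carried PNM differed from those without its reporter, LacZ mCherry+ against LacZ mCherry- cells. Both sorts also differed in acinar, endothelial and stromal markers (below), so a raised gene need not be one that PNM itself raised. Iapp, the amyloid peptide that beta cells release with insulin (chromosome 6, 142298423 to 142303961, plus strand), rose from 11.7 ± 3.98 to 327 ± 92.9 CPM (n = 4 each; log2 4.73 ± 0.262, adjusted p = 4.3e-12). Ins1 (chromosome 19, 52264297 to 52265476, plus strand) rose from 0.573 ± 0.484 to 11 ± 9.03 CPM (3.95 ± 0.64, adjusted p = 1.09e-05) and Ins2 from 2.15 ± 1.05 to 15 ± 7.93 (2.78 ± 0.651, adjusted p = 0.00134), low levels for the main products of a beta cell. Somatostatin (Sst), the hormone of delta cells, rose by 3.69 ± 0.445 (adjusted p = 1.87e-06) to 219 ± 47 CPM, ghrelin (Ghrl) by 4.47 ± 0.945 (adjusted p = 0.000601) and glucagon (Gcg), of alpha cells, by 1.37 ± 0.246 (adjusted p = 0.00012). The rise of Ins1 was 3.21 without replicate E of the mCherry+ cells, and those of Sst and Ghrl were 4.32 and 5.05 without B of the mCherry- cells. Ppy rose by 0.95 ± 0.349 (adjusted p = 0.0343), a call that was lost when replicate A (0.0882) or B (0.109) of the mCherry- cells or A (0.053), E (0.156) or F (0.0557) of the mCherry+ cells was left out.

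Regulators of islet development changed with the hormones. Insm1 rose by 5.41 ± 0.229 (adjusted p = 2.84e-14), Nkx2-2 by 2.79 ± 0.154 (adjusted p = 3.5e-14), Fev by 6.29 ± 0.512 (adjusted p = 4.85e-11) and Myt1 by 5.30 ± 0.387 (6.22 without replicate B of the mCherry- cells, which leaves 2 counts there). Among the highest changes were the water channel Aqp8 (7.18), Cryba2, the vesicle gene Rab3c and Th. Cryba2 had 321 counts in mCherry+ and 1 in mCherry- cells, a ratio per total count of 417 (95% interval from counting error alone 74.2 to 16500), and Rab3c 351 and 3, a ratio of 152 (51.5 to 740). Th rose by 6.29, but all 5 of its mCherry- counts lay in replicate B, and without replicate A of the mCherry+ cells the rise was 5.69. Of 19 beta cell genes, 15 were raised, 1 lowered and 3 neither. The lowered one, chosen after its values were seen, was Nkx6-1 (-1.39). Adjusted over the list alone, 16 were raised and 1 lowered (list test adjusted p = 1.36e-15, 0.0033 with an estimated correlation). Of 24 endocrine progenitor genes, 16 were raised, 5 lowered and 3 neither (17 and 6 adjusted over the list alone; list test adjusted p = 2.06e-07). The 18 other islet hormones and subtype genes had 12 raised, 3 lowered and 3 neither (12 and 4 adjusted over the list alone; adjusted p = 0.0181), with transthyretin (Ttr) up by 3.74 ± 0.361 and Hhex, a delta cell regulator, at -1.53 ± 0.205. That last list call was lost at adjusted p = 0.311 with an estimated correlation.

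Genes of regulated secretion and neuronal genes near REST sites rose together. All 28 secretory granule and exocytosis genes were raised, by a median of 3.45 (28 adjusted over the list alone; list test adjusted p = 2.17e-26), among them complexin 2 (Cplx2, 3.22 ± 0.162, adjusted p = 7.92e-15), Pclo (4.59 ± 0.277) and carboxypeptidase E (Cpe, 2.33 ± 0.139). Of 34 RE1-bearing REST target genes, 31 were raised and 3 neither (31 adjusted over the list alone), at a median of 3.92 (list test adjusted p = 2.17e-26), with Rundc3a at 5.14 ± 0.214 (adjusted p = 2e-15), the neurofilament gene Nefm at 4.95 ± 0.241 (adjusted p = 7.4e-15) and synapsin (Syn1) at 2.90.

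**Figure D2:**
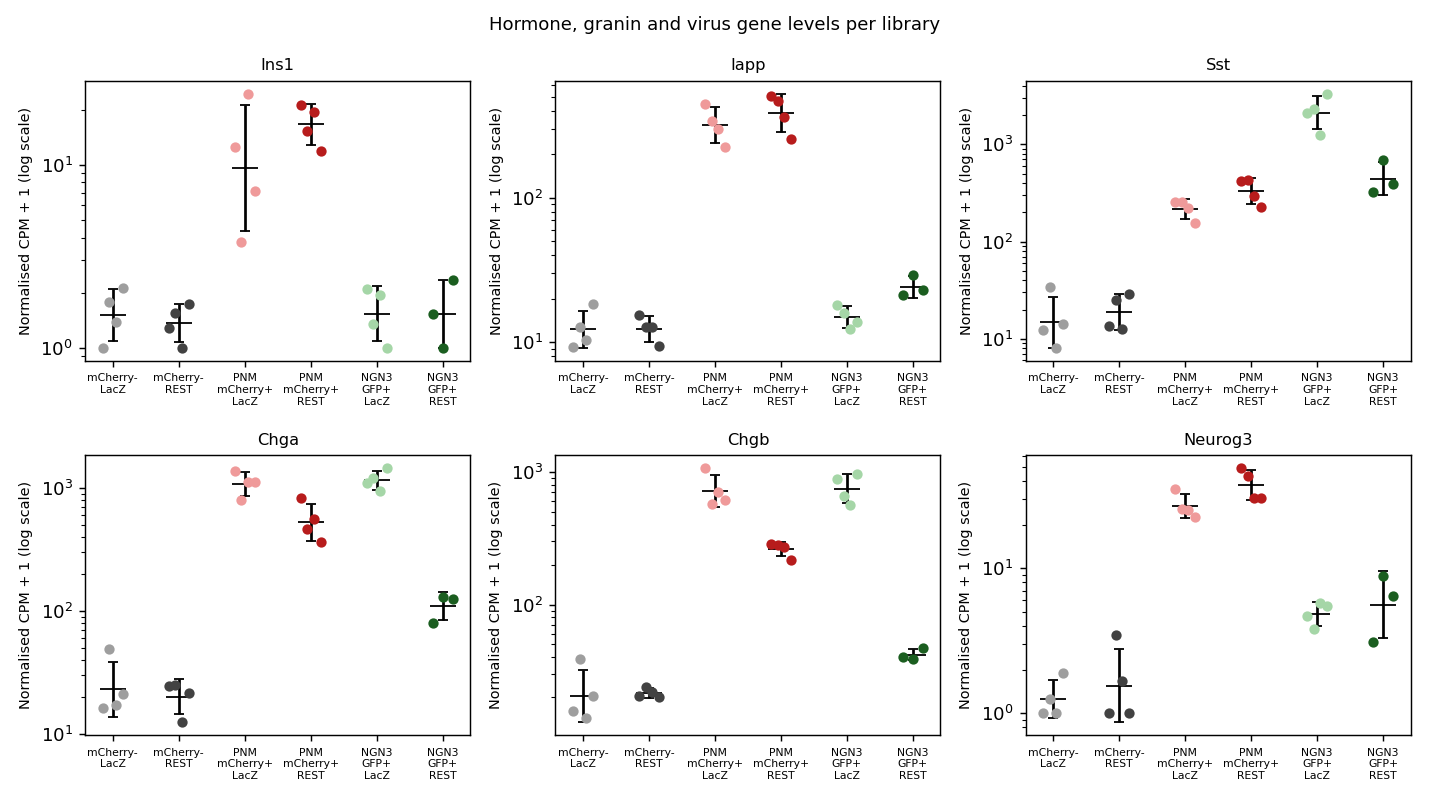
Levels of key genes (CPM + 1, log axis) in the 6 groups, with points for libraries and bars for mean ± SD on the log2 scale. Iapp is at 327 CPM in PNM mCherry+ and 14.1 in NGN3 cells with LacZ, while Sst is at 219 and 2235.

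Acinar genes were higher, not lower, in the mCherry+ cells. Of 35 acinar genes, 33 were raised, 1 was lowered and 1 neither (33 and 1 adjusted over the list alone), at a median of 3.75 (list test adjusted p = 8.34e-16, lost at adjusted p = 0.0868 with an estimated correlation). The elastase Cela1 went from 22.4 ± 8.42 to 265 ± 44.5 CPM (n = 4 each; 3.51 ± 0.251, adjusted p = 3.19e-10) and the protease precursor Ctrb1 stood at 9072 ± 4010 against 1490 ± 490 CPM. Gata4 rose by 2.83 ± 0.163 (adjusted p = 3.32e-14) and Gatm by 1.93. Tff2, also on the acinar list, rose by 5.16 ± 0.474 (adjusted p = 5.21e-08), or by 6.46 without replicate B of the mCherry- cells. Nupr1 (-0.85), the lowered gene, was chosen after its values were seen. The ductal and epithelial plasticity genes, 30 in all, had 15 lowered, 5 raised and 10 neither (15 and 5 adjusted over the list alone). Their list test gave adjusted p = 0.00429, lost at adjusted p = 0.41 with an estimated correlation. Among them were Bicc1 at -2.46 ± 0.17, vimentin (Vim) at -2.10 ± 0.2 and Prom1 at 1.48.

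Endothelial and stromal markers were lower in the mCherry+ cells. All 12 endothelial markers were lowered (12 adjusted over the list alone; median -4.30, list test adjusted p = 3.34e-19), among them the junction gene Cdh5, at 115 ± 36.5 in mCherry- and 2.86 ± 1.45 CPM in mCherry+ cells (n = 4 each; -5.33 ± 0.286, adjusted p = 7.36e-14), Emcn (-5.02 ± 0.296), Tie1 (-5.11) and Esam (-3.14). Fabp4 (-5.19 ± 0.385) and Sox18 were also among the lowest. Sox18 had 249 counts in mCherry- and 3 in mCherry+ cells, 64-fold lower per total count (95% interval from counting error alone 21.6 to 312). Without replicate E of the mCherry+ cells, which leaves 1 count there, its fit gave -6.73. All 13 stromal markers were lowered (13 adjusted over the list alone; median -1.86, list test adjusted p = 1.67e-09, lost at adjusted p = 0.0868 with an estimated correlation), with Sparc at -1.86 ± 0.17, Pdgfrb at -2.60 and Postn at -2.62 ± 0.247. In all, 2687 of 11384 genes were raised and 2461 lowered (45.2%), 1234 and 1002 of them by at least 2-fold. Of the 10 lists that passed, beta cell, endocrine progenitor, secretory granule, RE1-bearing and endothelial held with an estimated correlation.

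**Figure D3:**
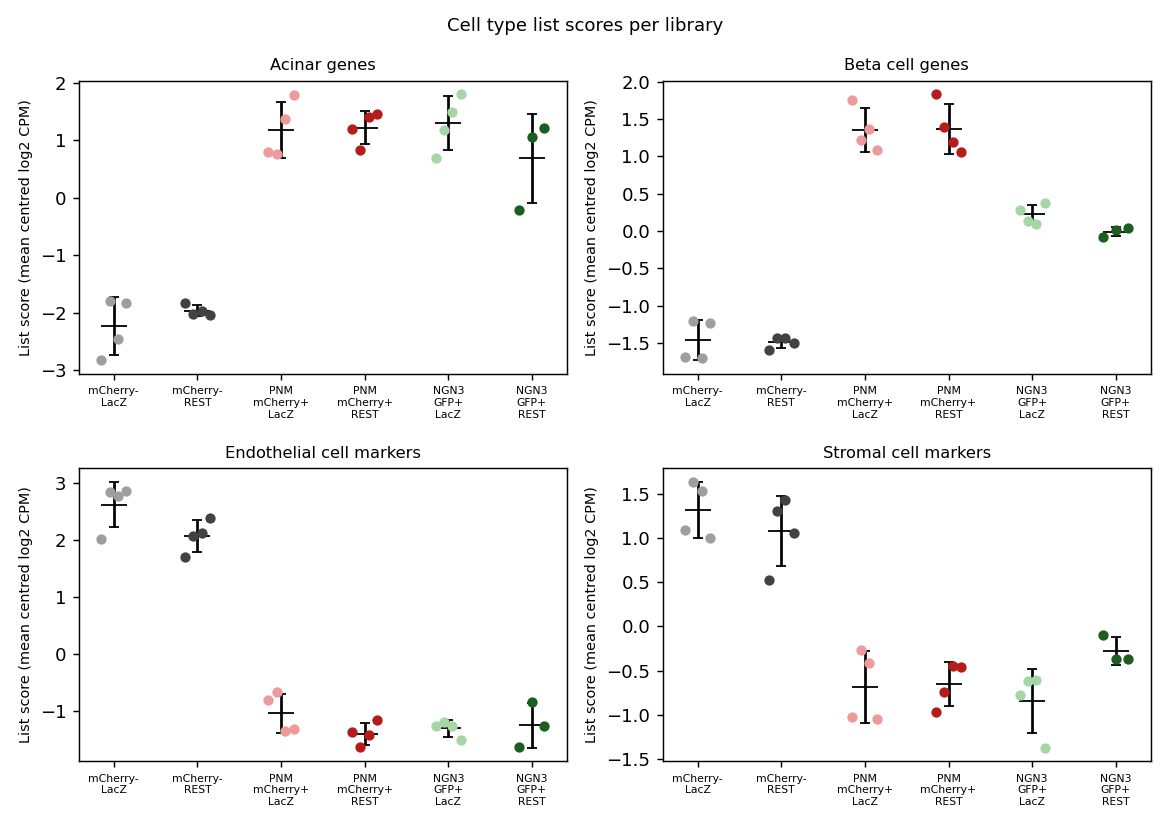
List scores (mean of centred log2 CPM) of cell type lists in each library, by group, with mean ± SD. The endothelial and stromal scores are highest, and the acinar score lowest, in the 8 mCherry- libraries.

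The same contrast with REST asked whether these genes still differed between the sorts when REST was present. Iapp was 34.2-fold, Ins1 37.4-fold, Sst 18-fold and Ghrl 85.3-fold higher in mCherry+ than in mCherry- cells with REST, and all were called. Insm1 was 49.7-fold higher, and the gut hormone Gip 149-fold and the receptor Insrr 191-fold. The folds of Ghrl and Gip moved when 1 library was left out. Ghrl had 4 counts in the mCherry- cells, and was 54.5-fold higher without replicate A of the mCherry+ cells and 197-fold without B of the mCherry- cells, which leaves 1 count there. Gip was 69.1-fold higher without A of the mCherry+ cells. In all, 2538 genes rose and 2340 fell. There were 2019 genes raised in both arms (599 by chance) and 1915 lowered in both (506 by chance), with 2 and 1 in opposite directions. The log2 differences correlated across genes (Pearson 0.94), and genes are not independent replicates. Of 19 beta cell genes, 16 were raised, 1 lowered and 2 neither (16 and 1 adjusted over the list alone; list test adjusted p = 3.83e-18). Of 34 RE1-bearing genes, 24 were raised and 10 neither (25 adjusted over the list alone; adjusted p = 1.53e-12; median 2.26, or 2.25 with Bsn, at 0 counts in 1 group, at its bound), and of 28 secretory granule genes 24 were raised, 1 lowered and 3 neither (24 and 1 adjusted over the list alone; adjusted p = 8.04e-16).

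Scg2, a granule protein precursor, was the lowered secretory granule gene with REST (-0.82) and was chosen after its values were seen. That call was lost without replicate F of the mCherry- cells (0.057) or A (0.062) or B (0.0642) of the mCherry+ cells. The p53 target genes, 10 raised, 1 lowered and 8 neither of 19 (11 and 3 adjusted over the list alone), passed at adjusted p = 0.00318, lost at adjusted p = 0.219 with an estimated correlation. The proliferation genes, 10 lowered and 20 neither of 30 (7 adjusted over the list alone), passed at adjusted p = 0.0195 and were lost at adjusted p = 0.526 with an estimated correlation, or at 0.0839 without replicate A of the mCherry- cells. The list test on acinar genes, 31 raised, 1 lowered and 3 neither of 35 (31 and 1 adjusted over the list alone), gave adjusted p = 7.7e-16, lost at adjusted p = 0.0781 with an estimated correlation. The 12 endothelial markers were all lowered (12 adjusted over the list alone; adjusted p = 6.08e-17; median -4.04, or -3.71 with Tek, at 0 counts in 1 group, at its bound). Of the 12 lists that passed with REST, the same 5 held with an estimated correlation as with LacZ.

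The effect of REST within PNM mCherry+ cells asked which genes of the reprogrammed cells REST holds down. Scg3, a granule protein (chromosome 9, 75643189 to 75684056, minus strand), fell 6.84-fold, from 25.8 ± 11 CPM with LacZ to 3.76 ± 0.416 with REST (n = 4 each; SE 0.269 on the log2 scale, adjusted p = 3e-07). Snap25, which drives vesicle fusion (chromosome 2, 136713453 to 136782428, plus strand), fell from 11.6 ± 2.31 to 1.49 ± 0.757 CPM (-2.84 ± 0.454, adjusted p = 0.000554), Unc13a, which primes vesicles, fell too (-2.89 ± 0.478, adjusted p = 0.000735), and the adhesion gene Celsr3 fell from 25.4 ± 7.42 to 3.87 ± 0.944 CPM (-2.65 ± 0.313, adjusted p = 1.22e-05). Srrm3, a neuronal splicing factor (-2.68 ± 0.368), Actl6b, a neuronal chromatin subunit (-2.51 ± 0.371), Sez6 (-2.31 ± 0.333), Disp2 (-2.16 ± 0.288), Ap3b2 (-1.90 ± 0.25), Scg5 (-1.59 ± 0.218) and Sez6l2 (-2.06 ± 0.33) fell too, as did the neuropeptide precursor Vgf, 4.61-fold. Stmn3 (-2.13 ± 0.466, adjusted p = 0.0325) kept its call in 1 of the 8 fits that left out 1 library, that without replicate E of the LacZ cells, with adjusted p-values of 0.057 to 0.111 in the others.

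With REST, 47 genes fell and 4 rose in PNM mCherry+ cells, of 11384 tested. With the replicate letter as a block, which the pairing of these libraries asks for, 62 fell and 16 rose, 78 in all. The 51 calls became 27 without replicate A of the LacZ cells, 31 without E and 32 without F of the REST cells. Phgr1 rose by 1.32 ± 0.271 (adjusted p = 0.0135; lost without replicate A, 0.0683, or B, 0.0642, of the LacZ or F, 0.0666, of the REST cells) and Slc25a39, a mitochondrial carrier, by 0.38 ± 0.0845 (adjusted p = 0.0288; lost without A, 0.0934, or B, 0.102, of the LacZ or E, 0.126, or F, 0.0566, of the REST cells). Fis1 (0.35, adjusted p = 0.0486) and Fjx1 (0.56 ± 0.127, adjusted p = 0.0319), the latter chosen after its values were seen, kept their calls in 1 and 2 of the 8 such fits (Fis1 without B of the REST cells, with 0.0674 to 0.191 otherwise; Fjx1 without E of the LacZ or F of the REST cells, with 0.0599 to 0.2 otherwise).

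The RE1-bearing REST target genes fell as a list. Of 34, 20 were lowered and 14 neither (23 lowered and 1 raised adjusted over the list alone), at a median of -1.09 (list test adjusted p = 1.61e-50, 6.97e-05 with an estimated correlation). Of 28 secretory granule genes, 14 were lowered and 14 neither (16 lowered and 1 raised adjusted over the list alone), at a median of -0.85 (adjusted p = 5.93e-29, 0.00344 with an estimated correlation). Both list calls held whichever library was left out. Of the 47 lowered genes, 20 were RE1-bearing, 14 were secretory granule genes and 21 were on neither list. Of the 18 secretory granule genes that are not on the RE1-bearing list, 6 were lowered. The chromogranins were chosen after their values were seen. Chgb (chromosome 2, 132781278 to 132795079, plus strand) fell from 741 ± 224 to 262 ± 31.7 CPM (-1.50, adjusted p = 0.00177). Chga (chromosome 12, 102554969 to 102565028, plus strand), at 1101 ± 233 and 552 ± 199 CPM, did not pass (-1.0, adjusted p = 0.221), though it was lower with REST in 4 of 4 letter pairs. Within letters A and B alone, with 2 libraries a group, the RE1-bearing median was -1.30 (28 of 34 genes negative) and within E and F -1.09 (31 of 34).

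**Figure D4:**
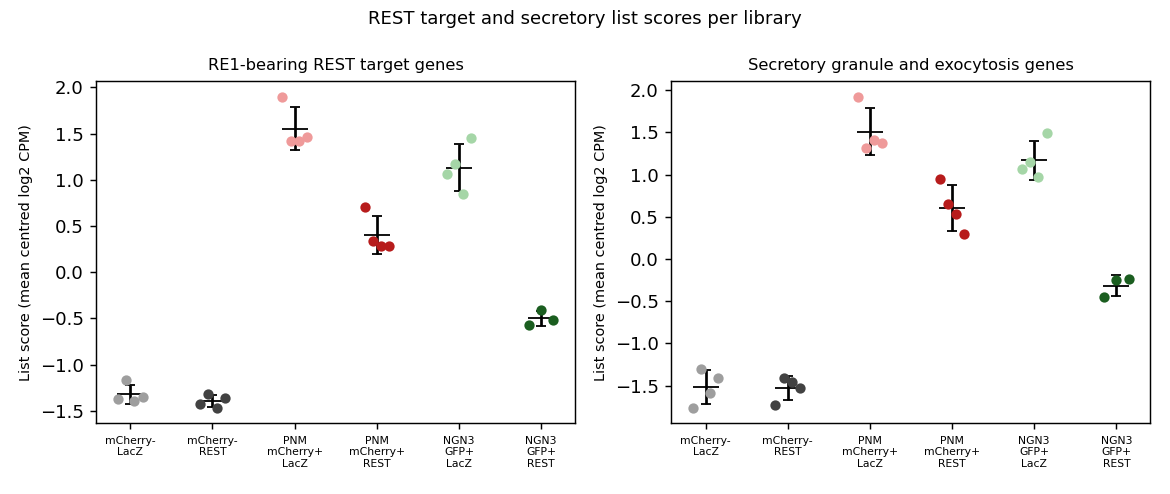
Scores of the RE1-bearing and the secretory granule lists (mean of centred log2 CPM) in each library, by group, with mean ± SD. The RE1-bearing score is 1.55 ± 0.233 with LacZ and 0.405 ± 0.205 with REST in PNM mCherry+ cells, 1.13 ± 0.252 and -0.50 ± 0.0834 in NGN3 cells.

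No islet hormone passed the test for REST in PNM mCherry+ cells, although most were somewhat higher with REST. Ins1 differed by 0.51 ± 0.405 (adjusted p = 0.69), Ins2 by -0.02 ± 0.508 (0.996), Sst by 0.64 ± 0.365 (0.554), Ghrl by 0.89 ± 0.53 (0.581), Iapp by 0.29 ± 0.2 (0.64), Gcg by 0.40 ± 0.236 (0.576) and Ppy by 0.45 ± 0.337 (0.673). By letter, Sst, Iapp, Gcg and Ppy were higher with REST in 4 of 4 pairs, Ins1 and Ghrl in 3 and Ins2 in 2. With the letter as a block none passed either (adjusted p from 0.35 for Gcg to 0.97 for Ins2). Of 19 beta cell genes 0 were called over all genes tested by edgeR and 1 was raised adjusted over the list alone (list median -0.02, adjusted p = 0.747), and Nkx2-2 differed by -0.10. The endothelial markers did not pass (adjusted p = 0.0612), yet did without replicate E (0.00547) or F (0.0135) of the LacZ or E (0.0368) or F (0.00679) of the REST cells, and with DESeq2 size factors (0.0459) or no filter on low counts (0.0493). The same held for the other islet hormones and subtype genes (0.0697; 2 raised adjusted over the list alone) without replicate A (0.0377) of the LacZ or E (0.0368) or F (0.00564) of the REST cells, for the ductal genes (0.269) without E of the LacZ (0.0137) or A of the REST cells (0.000457), for acinar genes (0.747) without F of the LacZ cells (0.0436) and for immediate early genes (0.747) without A of the REST cells (0.0371).

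The share of PNM-raised genes that REST lowered was also asked. PNM-raised here means called higher in mCherry+ than in mCherry- cells with LacZ. These sorts also differ in markers of other cell types, so PNM itself need not have raised every such gene. All 47 genes that fell with REST were among these 2687, 1.75% (exact 95% interval 1.29 to 2.32). By chance 11.1 would overlap, and 37 of the 47 were still raised in the mCherry+ cells with REST. With the letter as a block, 58 of the 62 genes that fell were among the 2821 raised, 2.06% (15.4 by chance). Both contrasts use the LacZ mCherry+ libraries, which alone couples them. With those libraries split into 2 and 2 the median share was 1.25% (27 genes), and from the genes raised in the REST arm it was 1.46% (37 genes). Of the PNM-raised genes 57.1% were negative with REST, the same as the 57.1% in 20 simulations without any REST effect (54.8 to 58.9), which called 0.05 lowered genes on average. The share was 1.05% without replicate A of the LacZ cells and 1.14%, 1.15% and 1.18% without B, E and F of the REST cells.

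REST in the PNM mCherry- cells served as the background. No gene was called there by edgeR (0 of 11384; 641 genes at an unadjusted p under 0.05, 5.63%), while DESeq2 called 1 and edgeR with the letter as a block 8 (2 raised, 6 lowered). The gene that DESeq2 called was the endothelial Emcn, chosen after its values were seen, at 80.9 ± 28.9 CPM with LacZ and 37.4 ± 6.17 with REST (n = 4 each; -1.13, adjusted p = 0.0525 by edgeR and 0.0438 by DESeq2). It passed without replicate A of the LacZ cells (0.00701), where there were 2 calls. The RE1-bearing genes had a median of -0.01 (adjusted p = 0.4) and the secretory granule genes -0.05 (adjusted p = 0.838). With LacZ these lists were already lower in mCherry- than in mCherry+ cells, by medians of 3.92 and 3.45. Their genes thus had less room to fall, and these values do not show that REST leaves them unchanged. The sort was on mCherry, which marks the PNM virus, so it does not show whether these cells took up the REST virus. Of the 47 genes lowered in mCherry+ cells, 0 were called here by edgeR and 26 were negative.

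A few other lists passed in the mCherry- cells at the preset correlation, with 0 members called by edgeR, and none held with an estimated correlation. The endothelial markers fell by a median of -0.64 with all 12 lower (12 neither; 7 adjusted over the list alone; adjusted p = 1.62e-11, lost at adjusted p = 0.0559 with an estimated correlation). The p53 targets had a median of -0.23 (19 neither; 2 adjusted over the list alone; adjusted p = 6.05e-05, lost at adjusted p = 0.194 with an estimated correlation). The stromal markers (median -0.23, 13 neither; adjusted p = 0.0137, lost at adjusted p = 0.725 with an estimated correlation) did not pass without replicates B (0.199) or E (0.108) of the LacZ or A (0.577) of the REST cells. The Notch pathway genes (median -0.22, 16 neither; adjusted p = 0.0145, lost at adjusted p = 0.0776 with an estimated correlation) did not pass without E (0.108) or F (0.0655) of the LacZ cells or without the filter on low counts (0.086). Acinar genes (median 0.01, 35 neither; adjusted p = 0.0196, lost at adjusted p = 0.822 with an estimated correlation) did not pass without A (0.463) or E (0.201) of the LacZ or A (0.195) of the REST cells. Proliferation genes (0.203) passed without A of the LacZ (0.00611) or E (0.00257) or F (0.0309) of the REST cells. Immediate early genes (0.0824) passed without A (0.0181) or E (0.049) of the REST cells and with the letter as a block (0.0345). So did the ductal genes (0.153) with the block (0.0205).

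Whether REST acted differently in mCherry+ and mCherry- cells was tested as a difference of differences. Gnptg (chromosome 17, 25233331 to 25240124, minus strand), a subunit of the enzyme that tags lysosomal proteins, was the single call of edgeR (-1.09 ± 0.173, adjusted p = 0.00776; 620 genes at an unadjusted p under 0.05, 3 lowered by DESeq2 and 4 with the letter as a block). It went from 197 ± 37.5 to 107 ± 5.11 CPM in mCherry+ and from 38.3 ± 4.47 to 44.5 ± 2.92 in mCherry- cells (n = 4 each). It kept its call whichever library was left out. Without replicate B or F of the LacZ mCherry- cells there were 2 calls (with Chgb, at 0.0473 without B), and 3 without B of the REST mCherry+ cells. The secretory granule genes (median -0.58, 28 neither, 8 adjusted over the list alone) passed at adjusted p = 2.02e-11, lost at adjusted p = 0.114 with an estimated correlation, and the 34 RE1-bearing genes (median -0.90, 34 neither, 7 adjusted over the list alone) at adjusted p = 6.21e-11, lost at adjusted p = 0.114 with an estimated correlation. Both lists were already lower in mCherry- cells, which left less room to fall there. The test cannot tell that apart from a different action of REST. Whether the mCherry- cells took up the REST virus was not measured here, so that is open too. The p53 targets (median 0.23, 19 neither, 1 adjusted over the list alone) passed at adjusted p = 0.00524, lost at adjusted p = 0.617 with an estimated correlation, and also without E (0.0761) or F (0.1) of the REST mCherry- or B (0.0807) of the REST mCherry+ cells.

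Other lists passed this test of a difference when some library was left out. The stromal markers (0.136) passed without A (0.036) or F (0.0211) of the LacZ mCherry-, B (0.00192) or E (0.0301) of the LacZ mCherry+, B (0.0311) or E (0.0184) of the REST mCherry- or A (0.0169) of the REST mCherry+ cells, and with the letter as a block (0.00311). Proliferation genes (0.278) passed without A of the LacZ mCherry- (0.0327), E (0.039) or F (0.00295) of the LacZ mCherry+ or E of the REST mCherry- cells (0.0184). Acinar genes (0.278) passed without B (0.0154) or F (0.0211) of the LacZ mCherry- or B of the LacZ mCherry+ cells (0.0248). Endocrine progenitor genes (0.138) passed without F of the REST mCherry+ cells (0.0296).

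In NGN3 cells the same question was asked of REST where Neurog3 was the only reprogramming gene. Snap25 fell from 14.4 ± 6.54 CPM with LacZ (n = 4) to 0.265 ± 0.458 with REST (n = 3; adjusted p = 5.13e-06). It had 189 counts with LacZ and 3 with REST, all 3 in replicate B, 37.3-fold lower per total count (95% interval from counting error alone 12.6 to 182). Cartpt, a neuropeptide precursor (chromosome 13, 99898489 to 99901091, minus strand), fell from 33.4 ± 7.5 to 1.54 ± 1.04 CPM (-4.61 ± 0.371, adjusted p = 3.14e-09). Chgb fell from 765 ± 188 to 41.0 ± 4.09 CPM (-4.24 ± 0.305, adjusted p = 1.1e-07) and Chga from 1168 ± 215 to 111 ± 27.1 (-3.42 ± 0.37, adjusted p = 2.27e-05). Scg3 (-3.10 ± 0.31, adjusted p = 1.49e-07), Celsr3 (-3.41 ± 0.398), Cdk5r2 (-3.37), Ap3b2 (-3.11) and Scg2 (-2.23) fell as well, Vgf was 10.2-fold (16-fold without replicate B of the REST cells) and Disp2 7.86-fold lower, and the prohormone convertase Pcsk1 went from 58.6 ± 17.2 to 12.5 ± 4.39 CPM (-2.27 ± 0.334, adjusted p = 0.000234). In total 98 genes fell and 11 rose. The 109 calls became 45 (42 lowered) without replicate B of the REST cells and 68 (65 lowered) without F of the LacZ cells.

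Somatostatin (chromosome 16, 23889573 to 23890958, minus strand) was the hormone that REST lowered in NGN3 cells. Sst had 2235 ± 839 CPM with LacZ (n = 4) and 465 ± 193 with REST (n = 3), 4.81-fold lower (SE 0.412 on the log2 scale, adjusted p = 0.00742), a call lost without replicate B (0.1) or E (0.05) of the REST cells. Ins1 (-0.22, adjusted p = 0.979), Ins2 (1.28, 0.587), Iapp (0.74, 0.417), Ghrl (2.06, 0.0869) and Gcg (0.14) were not called. Nkx2-2 fell by 0.71 on the log2 scale (adjusted p = 0.0204; lost without replicate C, 0.0678, or F, 0.109, of the LacZ or B, 0.294, or C, 0.0596, of the REST cells). Of 19 beta cell genes 3 were lowered and 16 neither (4 adjusted over the list alone; adjusted p = 0.025, lost at adjusted p = 0.445 with an estimated correlation, and without B, 0.0733, or F, 0.075, of the LacZ or B, 0.141, of the REST cells).

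The RE1-bearing and secretory granule lists fell in NGN3 cells too. Of 34 RE1-bearing genes, 20 were lowered and 14 neither (25 adjusted over the list alone; median -1.76, or -1.65 with Sez6 and Syp, at 0 counts in 1 group, at their bounds; list test adjusted p = 1.83e-68, 1.65e-05 with an estimated correlation). Of 28 secretory granule genes, 15 were lowered and 13 neither (19 adjusted over the list alone), all 28 were negative and the median was -1.42 (adjusted p = 2.67e-58, 0.000105 with an estimated correlation). Of the 98 lowered genes 20 were RE1-bearing, 15 were secretory granule genes and 71 were on neither list. Without replicate B of the REST cells the RE1-bearing list still passed (adjusted p = 3.06e-54).

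Proliferation, acinar and stromal lists also passed in NGN3 cells, and the acinar call rested on 1 library. Of 30 proliferation genes, 2 were raised and 28 neither (19 adjusted over the list alone), at a median of 0.78 with 29 positive (adjusted p = 2.56e-18, at most 2.9e-09 with any 1 library left out, lost at adjusted p = 0.0889 with an estimated correlation). Tk1, of nucleotide synthesis, rose from 10.9 ± 1.14 to 22.5 ± 1.22 CPM (1.04 ± 0.175, adjusted p = 0.000644), and Pcna, the replication clamp, by 0.57 (adjusted p = 0.0471; lost without replicate B, 0.129, C, 0.117, or F, 0.123, of the LacZ or B, 0.7, of the REST cells). Stmn1 rose by 0.66 (adjusted p = 0.00773; 0.127 without B of the REST cells). The 35 acinar genes, 35 neither (4 adjusted over the list alone), had a median of -0.55 (adjusted p = 8.73e-07, lost at adjusted p = 0.439 with an estimated correlation and at 0.141 without B of the REST cells). The 13 stromal markers, 13 neither and 13 positive, had a median of 0.58 (adjusted p = 4.49e-07, lost at adjusted p = 0.273 with an estimated correlation; 0.000148 at most with any 1 library left out). Without replicate C of the REST cells the endocrine progenitor (0.012), other islet hormones (0.0192) and ductal lists (0.01) passed as well, the last also with the letter as a block (0.0367).

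Most genes called lower with REST in PNM cells were also called lower in NGN3 cells, while most called in NGN3 cells were not called lower in PNM cells. That contrast compares calls at a threshold and does not test a difference. There were 39 genes lowered in both, of 47 in PNM and 98 in NGN3 cells, where 0.405 would be by chance (Fisher's exact test, p = 1.4e-76). That p-value is descriptive, as it takes genes as independent and does not measure the spread between libraries. By edgeR 0 genes were raised in both, of 4 and 11. With the letter as a block 44 were lowered in both and 2 raised in both, of 16 and 31 (0.0436 by chance). All 47 genes lowered in PNM cells were negative in NGN3 cells, and 88 of 98 the other way. With the block these were 55 of 62 and 104 of 119. Of the 39, 34 fell more in NGN3 cells, at medians of -1.59 in PNM and -2.23 in NGN3 cells, and 17 were RE1-bearing. Over all genes the estimated log2 differences were nearly uncorrelated (Pearson 0.169, Spearman 0.00107, across genes, which are not independent replicates). Only 51 and 109 of 11384 genes were called, and error in the estimates of the others weakens such a correlation. It thus does not show that the REST effects were unrelated. The 39 became 23 without replicate A of the LacZ PNM cells and 25 without B or F of the REST PNM cells or B of the REST NGN3 cells.

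**Figure D5:**
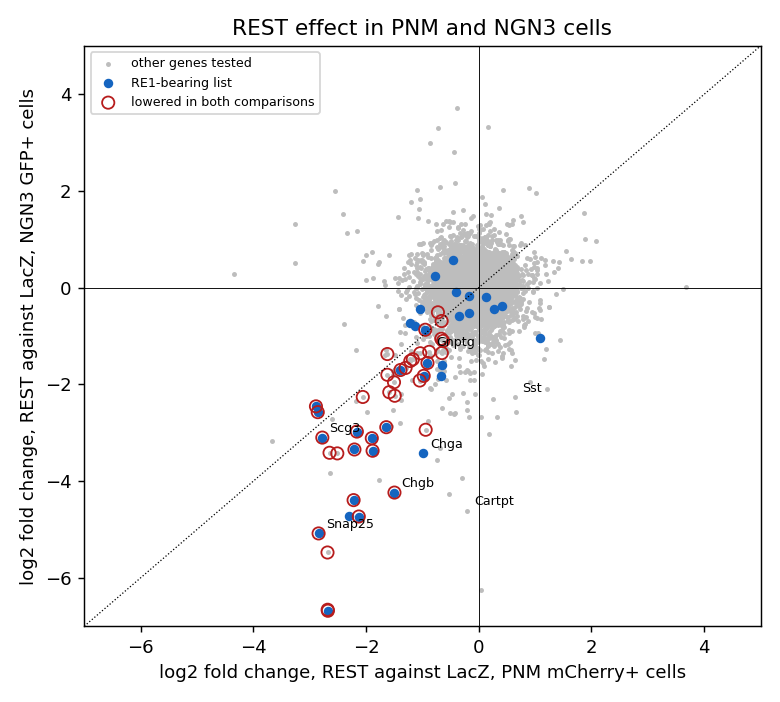
Log2 difference of REST against LacZ for each tested gene, in PNM mCherry+ cells (x) and NGN3 GFP+ cells (y), with RE1-bearing genes in blue and genes lowered in both circled in red. The 39 genes lowered in both lie in the lower left, 34 of them further down in NGN3 than in PNM cells.

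The difference between both REST effects was tested directly. Chgb fell less in PNM cells (difference 2.74 ± 0.365, adjusted p = 0.00283), and the effects on Cartpt differed too (4.40 ± 0.692, adjusted p = 0.00283). Cartpt had 1.81 ± 0.373 CPM with LacZ and 1.58 ± 0.598 with REST in PNM cells (n = 4 each), close to the 0.961 to 1.61 CPM that 3 counts make in these libraries, so it had little room to fall there. These were the 2 calls of edgeR (1072 genes at an unadjusted p under 0.05; 6 raised by DESeq2, and 5 called with the letter as a block). Cartpt lost its call without replicate A of the REST PNM cells (0.0901), which left 1 call, and there were 4 without A of the LacZ or B of the REST PNM cells. Sst (2.91, adjusted p = 0.114) and, chosen after its values were seen, Chga (2.42, adjusted p = 0.114) did not pass by edgeR, and did by DESeq2 (0.00313 and 0.00276). The secretory granule genes (median 0.52, 1 raised, 27 neither, 4 adjusted over the list alone) passed at adjusted p = 9.25e-08 and the RE1-bearing genes (0.75, 1 raised, 33 neither, 5 adjusted over the list alone) at 3.33e-07, each lost at adjusted p = 0.248 with an estimated correlation. Proliferation genes (-0.82, 30 neither, 12 adjusted over the list alone; adjusted p = 5.49e-12) were lost at adjusted p = 0.248 with an estimated correlation. Stromal markers (-0.69, 13 neither, 2 adjusted over the list alone; 9.71e-05) were lost at adjusted p = 0.36 with an estimated correlation. Acinar genes (0.52, 35 neither, 0 adjusted over the list alone by edgeR; adjusted p = 3.02e-05) were lost at adjusted p = 0.36 with an estimated correlation and at 0.152 without B of the REST NGN3 cells. The unfolded protein response genes (0.0931) passed without A of the LacZ PNM (0.047) or E of the REST PNM cells (0.0246).

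PNM and NGN3 cells with LacZ were compared to ask how cells with all 3 factors differ from cells with Neurog3. The viruses also differ in reporter and sort gate, and Neurog3 itself was higher in PNM cells. An effect of the added Pdx1 and Mafa cannot be told apart from these. Iapp was 23.5-fold higher in PNM cells (adjusted p = 3.41e-11), Ins1 17.1-fold (adjusted p = 3.03e-05) and Ins2 higher by 2.47 ± 0.626 (adjusted p = 0.00656), while Sst was 10.2-fold lower (adjusted p = 4.43e-06). Ins1 was 10.2-fold higher without replicate E of the PNM cells, and Ins2 higher by 3.52 without B of the NGN3 cells. Gcg (adjusted p = 0.499), Ppy (0.984) and Ghrl (0.828) were not called. The beta cell regulator Pax4 was higher by 4.16 (adjusted p = 2e-06) and Ero1lb 5.16-fold. Cck, a gut hormone (-3.15, adjusted p = 3.03e-09), Cartpt (-4.15, adjusted p = 1.74e-11) and Klk1 (-3.06) were lower. Of 11384 genes 1314 were higher and 1089 lower. Of 19 beta cell genes, 14 were higher, 3 lower and 2 neither (16 and 3 adjusted over the list alone; median 1.27, list test adjusted p = 2.26e-06, lost at adjusted p = 0.271 with an estimated correlation). The 3 lower ones, of which Isl1 and Pcsk1 were chosen after their values were seen, were Npy (-1.75), Isl1 (-1.67) and Pcsk1 (-1.53).

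The other lists were compared between PNM and NGN3 cells in the same way. Sez6 was higher by 3.61 and Tubb3 by 1.67, and of 34 RE1-bearing genes 8 were higher, 1 lower and 25 neither (12 and 1 adjusted over the list alone; adjusted p = 0.0283, lost at adjusted p = 0.827 with an estimated correlation, and without replicate A of the PNM, 0.24, or E of the NGN3 cells, 0.118). The 18 other islet hormones and subtype genes had 1 higher, 5 lower and 12 neither (1 and 6 adjusted over the list alone; adjusted p = 0.0402, lost at adjusted p = 0.827 with an estimated correlation). That call was lost without any single PNM library (0.0506 for A, 0.0817 for B, 0.0511 for E, 0.111 for F) and without F of the NGN3 cells (0.148), with the stricter filter (0.0885) or with the letter as a block (0.0604), which also ended the RE1-bearing call (0.0635). The 28 secretory granule genes, 9 higher, 2 lower and 17 neither (10 and 2 adjusted over the list alone; adjusted p = 0.103), passed without B of the PNM (0.0331) or F of the NGN3 cells (0.0213). Of 35 acinar genes 6 were higher, among them the regulator Nr5a2 (1.8) and the trypsinogen Prss1 (3.19), 5 lower and 24 neither (8 and 6 adjusted over the list alone; median -0.21, adjusted p = 0.627). Of 24 endocrine progenitor genes 8 were higher, 6 lower and 10 neither (9 and 6 adjusted over the list alone; adjusted p = 0.954). Of 30 ductal genes 5 were higher, 8 lower and 17 neither (6 and 10 adjusted over the list alone; median 0.02, adjusted p = 0.267). Of 16 Notch pathway genes 4 were higher, 1 lower and 11 neither (4 and 2 adjusted over the list alone; adjusted p = 0.574). Onecut1 (3.73) and the Notch target Hey1 (3.11) were higher in PNM cells, and the duct regulator Sox9 (-0.71) and the Notch ligand Jag1 (-1.07) lower.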

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

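All tests of explanations and all counts of other splits in this part were chosen only after the results they bear on were seen.

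Acinar genes were higher, and endothelial and stromal markers lower, in mCherry+ than in mCherry- cells. If the mCherry- fraction held fewer epithelial cells, genes of all epithelial cells would be higher in mCherry+ cells too. A list of 16 such genes had a median log2 difference of -0.033 (quartiles -0.332 and 0.27), against 3.75 (2.58 and 4.74) for the acinar genes. That list was written after the values of all but 1 of them had been seen, and Krt19 was left out after its value was seen, so the test decides nothing and this explanation stays open. All 25 endothelial and stromal markers tested were lower in mCherry+ cells, as endothelial and stromal cells in the mCherry- fraction would give. These markers are the pattern itself, so their count is no separate test of that explanation. Which epithelial cells took up the virus, and whether PNM itself changed the acinar genes, stays open, since the labels name no other cell type for either sort.

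RE1-bearing genes were lower with REST in both reprogrammed populations. A wrong label on a REST or LacZ library would let their scores overlap, yet the lowest LacZ library exceeded the highest REST library by 0.709 in PNM and 1.25 in NGN3 cells. Fewer converted cells in the REST mCherry+ sort would lower the genes that conversion raises. The 2638 genes raised with LacZ and outside the RE1-bearing and secretory granule lists had a median of -0.0373 (quartiles -0.238 and 0.113), against -1.09 (-2.15 and -0.5) for the RE1-bearing list. Acinar genes are among the 2638, and whether PNM raised them stays open, so that median alone does not decide. The beta cell and endocrine progenitor genes, mostly raised with LacZ, had medians of -0.02 and 0.01 with REST (list test adjusted p = 0.747 and 0.639). As lists they did not fall, unlike what fewer converted cells predict. This second test covers PNM cells alone, as no GFP- cells were measured. A candidate explanation that remains, as a hypothesis, is repression by REST at RE1 sites, and binding was not measured here.

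REST lowered RE1-bearing and secretory granule genes by more in NGN3 than in PNM cells. Leaving out any 1 of the 15 libraries left the RE1-bearing list at an adjusted p of at most 5.06e-05, with its median at 0.478 to 0.891. With an estimated correlation the adjusted p was 0.248 over all libraries, so the difference itself may not be firm. On unequal depth, a first single thinning to the lowest total gave a median of 0.36, below the bound of 0.377 that depth as the cause predicts, and the 30 thinnings reported and their rule were chosen afterwards: their median was 0.667 (95% of them 0.483 to 0.849, lowest 0.36, 29 of 30 above the bound), against 0.753 unthinned. A share of PNM cells without the REST virus stays open. Over the 34 genes lowered at least 4-fold in NGN3 cells no single share fitted (heterogeneity across n = 34 genes, Q 111 on 33 degrees of freedom, p = 2.18e-10), but that test assumes that PNM cells with REST fall as NGN3 cells do, on genes picked by their fall in NGN3 cells. The doses of both viruses in each cell, and the added Pdx1 and Mafa, remain open and untested.

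Other splits of the same libraries tested whether chance could give as many calls. The real split gave the most calls for mCherry+ against mCherry- cells with LacZ (5148 calls, highest other split 2, 1 of 35 splits as large) and with REST (4878, highest other 1, 1 of 35). The same held for REST in NGN3 cells (109, highest other 36, 1 of 35) and for PNM against NGN3 cells (2403, highest other 2, 1 of 35). A share of 1 in 35 is the smallest that these splits can give. Every other split also mixes the real groups, which widens the spread within its groups and lowers its calls. These counts therefore do not exclude chance by themselves. For REST in PNM mCherry+ cells another split gave more calls than the real one (51 calls, highest other 167, 2 of 35 as large). The 167 calls came from letters A and B against E and F, several times the real count, which points to a structure of these libraries by letter. Among the 8 splits that part all 4 letter pairs, the 7 others gave at most 0 calls by edgeR against 51 (78 with the letter as a block). For REST in mCherry- cells the count of splits decides nothing, because with 0 real calls by edgeR (641 genes at an unadjusted p under 0.05, 1 call by DESeq2) all 35 splits are as large by construction (highest other 8). Chance was not excluded for the difference between mCherry+ and mCherry- cells (1 call, highest other 1; 6 of 100 splits drawn) or for the difference between PNM and NGN3 cells (2 calls, highest other 14; 9 of 100).

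A few libraries lay far from the others of their group, in 6 of 126 sets of values checked. A set held a list score, the total or the level of a gene in the 4 libraries of a group. Chance would give 6.3 if the sets were independent, but they share libraries and some share genes. The count therefore does not show whether these libraries, mostly replicate A, differ by chance. Replicate A of the LacZ mCherry+ cells had a secretory granule score of 1.925 (others 1.317 to 1.414), an RE1-bearing score of 1.901 (1.42 to 1.468) and an immediate early score of -0.5624 (-0.2696 to -0.214). Replicate A of the REST mCherry+ cells had an RE1-bearing score of 0.7105 (0.284 to 0.3389). Replicate A of the LacZ mCherry- cells had an endothelial score of 2.026 (2.771 to 2.854). Chga in replicate B of the LacZ mCherry- cells had 47.65 CPM (15.17 to 19.95).

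Tests of a difference between REST effects passed for some genes and lists. Between mCherry+ and mCherry- cells these were Gnptg (log2 -1.09), the secretory granule genes (adjusted p = 2.02e-11, lost at adjusted p = 0.114 with an estimated correlation), the RE1-bearing genes (6.21e-11, lost at 0.114) and the p53 targets (0.00524, lost at 0.617, and without replicate E, 0.0761, or F, 0.1, of the REST mCherry- or B, 0.0807, of the REST mCherry+ cells). The secretory granule and RE1-bearing genes were already lower in mCherry- cells, with less room to fall there. Between PNM and NGN3 cells they were Cartpt (4.40; adjusted p = 0.0901 without replicate A of the REST PNM cells; near the floor of 3 counts in PNM cells, where it had little room to fall), Chgb (2.74), and the secretory granule (9.25e-08), RE1-bearing (3.33e-07), proliferation (5.49e-12), stromal (9.71e-05) and acinar lists (3.02e-05; 0.152 without B of the REST NGN3 cells). With an estimated correlation all 5 were lost, at 0.248 for the first 3 and 0.36 for the stromal and acinar lists.

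Another 4 lists that passed between PNM and NGN3 cells each depended on several libraries. The 19 beta cell genes (0.0148, 0 called by edgeR and 3 adjusted over the list alone, lost at adjusted p = 0.36 with an estimated correlation) did not pass without F of the LacZ PNM (0.109), A of the REST PNM (0.156), F of the LacZ NGN3 (0.0733) or B of the REST NGN3 cells (0.0642). The 24 endocrine progenitor genes (0.0383, 2 adjusted over the list alone, lost at adjusted p = 0.377 with an estimated correlation) did not pass without B (0.0899) or F (0.107) of the LacZ PNM, A (0.238) or B (0.0912) of the REST PNM, F (0.106) of the LacZ NGN3, or B (0.276) or E (0.151) of the REST NGN3 cells. The 18 other islet hormones and subtype genes (0.0101, 2 adjusted over the list alone, lost at adjusted p = 0.36 with an estimated correlation) did not pass without A of the REST PNM (0.0675), F of the LacZ NGN3 (0.0785) or E of the REST NGN3 cells (0.0875). The 12 endothelial markers (0.0383, 0 adjusted over the list alone by edgeR, lost at adjusted p = 0.396 with an estimated correlation) did not pass without A (0.098) or B (0.0899) of the LacZ PNM, B (0.14) of the REST PNM, F (0.0785) of the LacZ NGN3, or C (0.448) or E (0.0875) of the REST NGN3 cells.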

How the results depend on the processing

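Thinning the libraries, DESeq2 and leave-one-out fits for single genes, and leave-one-out fits for the overlap and the share were chosen only after the results were seen; the other alternatives were planned.

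Among 235 combinations of a named gene and a comparison, 0 of the 183 called by edgeR changed direction under any alternative run, and 17 of the 52 not called did, without being called. Of the 183, 163 kept their call whichever library was left out and 20 lost it in at least 1 such fit; of the 52 not called, 2 gained one. With DESeq2 230 of 235 kept their side of the threshold, with DESeq2 size factors 232 and with the letter as a block 234. Without the filter on low counts 229 did. With the stricter filter 219 of 221 kept it, with only the groups compared in the model 201 of 216 and after thinning 214 of 224. Sst with REST in NGN3 cells was among the lost calls with only the groups compared (adjusted p = 0.106). The medians of all genes moved by at most 0.0139 between scalings.

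Numbers of called genes moved by more than 1.5 times in the comparisons with few calls, and the cause was not tested. REST in mCherry- cells, with 0 calls by edgeR (641 genes at an unadjusted p under 0.05), gave 1 with DESeq2, 1 with its size factors, 1 without the filter and 8 with the block. REST in PNM mCherry+ cells gave 78 with the block, against 51. The difference between mCherry+ and mCherry- cells (1) gave 3 with DESeq2 and 4 with the block, and that between PNM and NGN3 cells (2) gave 6, 5 and, after thinning, 1. The share of PNM-raised genes lowered by REST was 1.25% with the LacZ libraries split into 2 and 2, against 1.75%; its 2 libraries per contrast leave fewer samples.

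The number of lists that passed depended on the correlation assumed between genes. With an estimated correlation it was 5 in place of 10 for mCherry+ against mCherry- cells with LacZ, 5 in place of 12 with REST, 2 in place of 6 for REST in NGN3 cells, and 0 in place of 5 for REST in mCherry- cells, of 3 for its difference to mCherry+ cells, of 3 for PNM against NGN3 cells and of 9 for the difference between PNM and NGN3 cells, all with camera. With fry, which asks whether a list moves on balance and compares it with no other genes, the numbers were 16, 3 for REST in NGN3 cells, and 0 in mCherry- cells and for both differences. With the block 1 of the 3 lists passed for PNM against NGN3 cells (RE1-bearing 0.0635, other islet hormones 0.0604). Between the REST effects in PNM and NGN3 cells, the endothelial call was lost with the block (0.0612) and the stricter filter (0.0751), and the endocrine progenitor call with that filter (0.0751) and with none (0.0751). No list count was made for DESeq2, for thinning or for only the groups compared.

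Leaving out each library in turn gave 4664 to 4905 calls for mCherry+ against mCherry- cells with LacZ and 4244 to 4667 with REST. REST gave 27 to 44 in PNM mCherry+, 0 to 2 in mCherry- and 45 to 117 in NGN3 cells. The lowest of these came without replicate A of the LacZ mCherry+ cells (27) and B of the NGN3 REST cells (45). The differences gave 1 to 3 between mCherry+ and mCherry- and 1 to 4 between PNM and NGN3 cells, and PNM against NGN3 1970 to 2390. Lists that passed numbered 10 to 11, 11 to 12, 2 to 4, 2 to 7, 2 to 5, 4 to 9, 1 to 3 and 5 to 10 for the 8 comparisons in this order: mCherry+ against mCherry- with LacZ and REST, REST in PNM mCherry+ and mCherry- cells, their difference, REST in NGN3 cells, PNM against NGN3, and the difference of REST effects between them. The overlap of lowered genes was 23 to 38 and the share 1.05 to 1.94%.

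After 1 thinning to 1562738 counts per library, 10 of the named calls were lost. In simulated data at the real depths, 12.5% of 1.5-fold differences between PNM and NGN3 REST effects were called.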

Other observations

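The results in this part come from planned list tests; single genes outside the rule for named genes are said to have been chosen after their values were seen, and no further hypothesis was tested.

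Stress and signalling genes also differed between LacZ mCherry+ and mCherry- cells. Immediate early and heat shock genes, which respond within minutes to growth factors and handling, were mostly lower: of 21, 13 were lowered, 1 raised and 7 neither (13 and 1 adjusted over the list alone; median -0.75, adjusted p = 9.51e-06, lost at adjusted p = 0.0954 with an estimated correlation). Dusp1, a phosphatase that ends such signals, was at -1.72 ± 0.157 and Fosl1 at -1.48 ± 0.15. The raised one, Jund, chosen after its values were seen, was at 0.29 and lost its call in 6 fits that left out 1 library (adjusted p of 0.0746 to 0.192): A, B or E of the mCherry- and B, E or F of the mCherry+ cells. Of 24 unfolded protein response genes, 10 were raised, 3 lowered and 11 neither (12 and 4 adjusted over the list alone; adjusted p = 0.231). Sel1l, which serves the removal of misfolded proteins, went from 122 ± 24.4 to 1113 ± 282 CPM (n = 4 each; 3.18 ± 0.242), the chaperone Hsp90b1 rose by 0.92 ± 0.0991, and Cebpb, a stress-induced transcription factor, fell from 474 ± 24.8 to 138 ± 17 CPM (-1.78 ± 0.126).

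Of 19 p53 targets 9 were raised, 3 lowered and 7 neither (10 and 4 adjusted over the list alone; adjusted p = 0.108, and 0.0484 without replicate B of the mCherry- cells), with Sesn1 at 2.39 ± 0.196, the cell cycle inhibitor Cdkn1a at 0.86 ± 0.116 and Bbc3 at 1.14. Of 30 proliferation genes 8 were lowered and 22 neither (2 adjusted over the list alone; adjusted p = 0.108, and 0.0204 without replicate B of the mCherry+ cells), with the replication genes Mcm2 at -0.62 ± 0.16 and Mcm3 at -0.53. The 22 interferon response genes went both ways, 6 raised, 4 lowered and 12 neither (6 and 4 adjusted over the list alone; adjusted p = 0.563). The antiviral Rsad2 went from 0.640 ± 0.253 to 14.2 ± 3.28 CPM (4.43 ± 0.378, adjusted p = 5.09e-11), Oasl1 rose by 1.40 ± 0.322 and Usp18 by 1.16 ± 0.324, while Ifit3, chosen after its values were seen, was at -1.05 and lost its call without replicate A of the mCherry- cells (0.0521).

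Of 16 Notch pathway genes 4 were raised, 8 lowered and 4 neither (4 and 8 adjusted over the list alone; median -0.37 but mean 0.01, adjusted p = 0.412): the receptor Notch1 was at -1.72 ± 0.162, and its modifiers Lfng at 2.52 ± 0.231 and Dtx1 at 3.14 ± 0.338. Of 13 REST corepressor genes 4 were raised and 9 neither (4 adjusted over the list alone; adjusted p = 0.343): Rcor2 by 1.5 ± 0.206, Kdm1a by 0.52, Smarca4 by 0.41 and Hdac2 by 0.54. Of 6 immune markers 2 were raised and 4 lowered (2 and 4 adjusted over the list alone; adjusted p = 0.236), with C1qa at 3.91 ± 0.504, Cd74 at -2.32 ± 0.341, Cd14 at -2.23 and Csf1r at -1.81. Of the 3 Schwann cell markers tested 1, the receptor Gfra3 (4.45 ± 0.57), was raised (1 adjusted over the list alone), too few for a list test.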
